A study of Homo sapiens with 6 samples.

How the data were processed

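Gene expression was measured on Affymetrix oligonucleotide arrays in 6 samples of 3 human cell lines, with 2 biological replicates per line. HES-3 is an established human embryonic stem (ES) cell line. IMR90 is a fibroblast line from human lung, and ESIMR90 is a line of induced pluripotent stem (iPS) cells, that is, cells made pluripotent by reprogramming, derived from IMR90. Per the labels' protocols, HES-3 and ESIMR90 were grown on Matrigel in mTeSR1 medium and IMR90 in a medium with serum, so the medium went with the cell type. RNA was extracted with TRIzol and columns and labelled with a 3' IVT kit, which copies RNA from its poly(A) tail, so that signals come mainly from the 3' end of each transcript. The labels call the replicates biological and say nothing more of how the cultures were separated, so p-values measure the spread between these samples.

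The deposited values were signal intensities on a linear scale, 1 per probe set (a group of short probes for 1 transcript). Per the submitters' processing notes they were made with the MAS5 algorithm, which corrects each array for background and scales it alone, in Affymetrix Expression Console 1.1. The mean of each deposited array after trimming 2% from either end lay between 500.05 and 500.07 (checked on the values), the result of scaling every array to 1 target. No detection calls were used here, so signal against the array's own median was used as the measure of brightness. The precision of every value is limited by the number of arrays.

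The platform annotation listed 1 gene symbol for 41091 of the 54675 probe sets, several for 1801 and none for 11721, and 62 were control probe sets. A probe set was kept if its signal lay above the median of its array on at least 2 of the 6 arrays, which left 31915, of which 25727 had 1 symbol. Each gene was represented by its kept probe set with the highest mean log2 signal, giving 13536 genes, 6762 of them with more than 1 kept probe set. Of these genes, 13520 matched the NCBI gene table by identifier and 0 symbols were replaced. Probe sets with several symbols were not named, and POU5F1 (OCT4) lay only on such a probe set. All columns of the value table belonged to a sample.

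Intensities were log2 transformed with no pseudocount and not normalised again. A linear model with 1 coefficient per line was fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, which left 3 residual degrees of freedom and added 5.21 from the prior across genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 13536 genes of each comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Adjusted p-values of genes in the text are limma's, differences are log2 differences ± standard error with n = 2 arrays per line, and levels are means of log2 signal converted back to the linear scale. Where both arrays of the dimmer line were at or under their array medians, the fold is given as at least the ratio of the brighter line's mean to the mean of those medians.

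A set of 29 gene lists, written from background knowledge, was fixed before the data were examined, as were the tests, the threshold, the rule for naming genes and all alternatives except 1. The lists covered core, naive and primed pluripotency, reprogramming factors, fibroblast and extracellular matrix, mesenchymal transcription factors and adhesion, positional identity (HOX, TBX and FOXF genes), contractile and smooth muscle, epithelial junction and identity, lung epithelium, endoderm, mesoderm, ectoderm and neural, trophoblast, endothelial, blood and macrophage, DNA replication and mitosis, cell cycle inhibitors and p53 targets, glycolysis, oxidative phosphorylation, cholesterol and lipid synthesis, DNA methylation and Polycomb, imprinted genes, genes near 20q11.21, immediate early response, heat shock and unfolded protein response, antigen presentation and interferon, metallothioneins, and genes reported to vary between iPS and ES lines. The lists share some genes. Each list with at least 5 tested members was tested with camera, limma's test of whether a set differs from all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with a correlation estimated from the 3 residual degrees of freedom, and with fry, which tests whether a set's genes move on balance in 1 direction. Because the estimated correlation rests on so few degrees of freedom, a call lost with it leaves open whether correlated genes made that call. For each list the number of called members was also counted with p adjusted over the list alone.

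Named genes were, per comparison and direction, the 5 with the largest difference among called genes above the array median on every array of both lines and with no overlap between the lines. The 5 brightest called genes with the dimmer line at or under its array medians on both arrays were added in each direction, then the 3 members of each list with the smallest adjusted p, and the reprogramming factors in every comparison. Levels of XIST and of genes on the Y chromosome are not reported here.

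The fitting was tested on simulated data in which 100 of 13536 genes were changed by 1.5 and 100 by 3 on the log2 scale. Of those changed by 3, the fit called 84% for ESIMR90 against IMR90, 83% for HES-3 against IMR90 and 84% for ESIMR90 against HES-3. Of those changed by 1.5 it called 57%, 46% and 42%, with 12, 7 and 7 false calls. Because both pluripotent lines were compared with the same IMR90 arrays, their agreement was also computed in 100 simulated draws without any difference.

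Alternatives were quantile normalisation, median centring, 3 other filters on dim probe sets, a pseudocount, a floor at the array median, 2 other ways to choose probe sets per gene, probe sets in place of genes, 2 other variance models, a fit of only the groups compared, the replicate number as a block, no minimum difference, limma's treat test against a difference of 1, and leaving out each array in turn. The ratio of the 3' to the 5' beta-actin control probe set as a covariate was added after seeing the data. No genome sequence was used here.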

Results

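The transcriptomes of human ES cells (HES-3), iPS cells (ESIMR90) and the fibroblasts from which the iPS cells were derived (IMR90) were compared on 6 arrays, 2 per line. The series asks how the reprogrammed line differs from its parental fibroblasts and from ES cells, and 3 comparisons follow from it: each pluripotent line against IMR90, and ESIMR90 against HES-3.

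Replicates correlated at r = 0.904 for ESIMR90, 0.896 for HES-3 and 0.929 for IMR90 (Pearson, log2 signal across all probe sets other than controls, which are not independent). The first array of ESIMR90 correlated more closely with the first of HES-3 (0.917) than with its own replicate. Correlations of either pluripotent line with IMR90 lay between 0.754 and 0.801. Between replicates, 11.6% of the genes differed by more than 2-fold in ESIMR90, 18.6% in HES-3 and 7.06% in IMR90. The median signal of an array was 101 and 126 in ESIMR90, 108 and 126 in HES-3, and 74.9 and 77.2 in IMR90. The ratio of the 3' to the 5' beta-actin control probe set, which increases when RNA is degraded or incompletely copied, was 8.48 and 3.90 in ESIMR90, 4.67 and 16.5 in HES-3, and 2.08 and 1.81 in IMR90. It was thus lowest in IMR90, so against IMR90 this ratio and the line are confounded, and using it as a covariate cannot separate them. For GAPDH the ratio was 2.52 on the second HES-3 array and between 0.996 and 1.64 on the others.

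Genes of the pluripotent state were far higher in the iPS cells than in the fibroblasts they came from. All 34 tested members of the core pluripotency list were called higher in ESIMR90 than in IMR90, with a median log2 difference of 6.57. LIN28A, an RNA-binding protein that blocks maturation of let-7 microRNAs, was at least 410-fold higher, SOX2, a transcription factor at the centre of the pluripotency network, at least 259-fold, and NANOG, another such factor, at least 105-fold. DPPA4, a chromatin-associated pluripotency marker, was at least 222-fold higher and SFRP2, a secreted modulator of WNT signalling, at least 96.5-fold. The brightest genes with IMR90 at or under its array medians also included the surface glycoprotein CD24 (at least 492-fold), L1TD1, an RNA-binding protein of ES cells (at least 299.8-fold), and TRIM71, a target of let-7 (at least 279-fold). Among genes measured in both lines, the largest increases were in the MIR302B probe set (7.78 ± 0.32), POU5F1B (7.68 ± 0.22), POU5F1P4 (7.05 ± 0.31), the junction protein CXADR (6.81 ± 0.25) and the de novo DNA methyltransferase DNMT3B (6.72 ± 0.28, a mean signal of 33010 against 312). The MIR302B probe set reads a longer transcript and not the mature microRNA. POU5F1B and POU5F1P4 are near-identical copies of POU5F1, and their probe sets, like that of CD24, are of the class that may cross-hybridise, so which copy gave the signal is uncertain. The core pluripotency list differed from the other genes at an adjusted p = 1.82e-17 with camera, and adjusted p = 0.0568 with an estimated correlation.

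The programme of connective tissue was correspondingly low in ESIMR90. Of 38 tested fibroblast and extracellular matrix genes, 35 were called lower than in IMR90 and 0 higher, with a median of −4.88. The matrix proteoglycan DCN differed by −7.85 ± 0.29, the collagen cross-linking enzyme LOX was at least 205-fold lower and NT5E (CD73), a mesenchymal surface enzyme, at least 120-fold lower. The calcium-binding protein S100A6 was at least 277-fold lower, the BMP antagonist GREM1 at least 222-fold, the collagenase MMP1 at least 205-fold and IGFBP7, a secreted binding protein of insulin-like growth factors, at least 159-fold. Among genes measured in both lines, the hyaluronan receptor CD44 (−7.23 ± 0.42), the caveolar protein CAV2 (−7.07 ± 0.46), the membrane repair protein MYOF (−6.95 ± 0.39), the smooth muscle actin ACTG2 (−6.67 ± 0.64) and IGFBP5 (−6.39 ± 0.57) fell furthest. Camera gave an adjusted p = 1.58e-20 for the fibroblast list, and adjusted p = 0.137 with an estimated correlation. THY1, S100A4 and FBLN1, named after their values were seen, were the members not called, at −1.001 ± 0.512, 0.28 ± 0.38 and −0.23 ± 0.39.

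Adhesion and cell shape genes changed in opposite directions. Of 25 epithelial junction and identity genes, 24 were called higher in ESIMR90, including E-cadherin (CDH1, at least 160-fold), the adhesion molecule EPCAM (8.02 ± 0.24) and the epithelial splicing regulator ESRP1 (at least 58.9-fold). Of 18 mesenchymal transcription factor and adhesion genes, 15 were called lower, including the receptor kinase AXL (−3.10 ± 0.25), the TGF-beta receptor TGFBR2 (−4.01 ± 0.33) and the fibronectin receptor subunit ITGA5 (−3.15 ± 0.29). TCF4, named after its value was seen, was the 1 member called higher (1.30 ± 0.21). Contractile and smooth muscle genes were lower in 11 of 12 cases, with the smooth muscle actin ACTA2 at −5.58 ± 0.42, the myosin light chain kinase MYLK at −3.89 ± 0.26 and TGFB1I1, a focal adhesion protein, at −4.82 ± 0.40. The epithelial, mesenchymal and contractile lists had adjusted p = 1.68e-13, 5.68e-08 and 1.27e-07, and adjusted p = 0.0824, 0.0824 and 0.230 with an estimated correlation. Positional identity genes were lower in 14 of 17 cases, with the lung mesenchyme factor FOXF1 at −6.06 ± 0.44, HOXB6, a homeobox gene of the trunk, at least 18.3-fold lower and the T-box factor TBX2 at least 7.49-fold lower. That list had adjusted p = 1.94e-07, and adjusted p = 0.417 with an estimated correlation.

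Cell cycle and chromatin genes differed by less. Of 36 DNA replication and mitosis genes, 23 were called higher in ESIMR90 and 0 lower, among them the replicative helicase components MCM3 (2.44 ± 0.29) and MCM5 (2.82 ± 0.38) and the replication initiation factor MCM10 (2.77 ± 0.40). Among 17 cell cycle inhibitors and p53 targets, 6 were lower and 1 higher: CDKN2A, which encodes the inhibitors p16 and ARF, was at least 9.20-fold lower, CDKN1A (p21) was at −3.09 ± 0.36 and the p53 target ZMAT3 at −2.19 ± 0.26. DNA methylation and Polycomb genes were higher in 10 of 21 cases and lower in 1, with the 5-methylcytosine oxidase TET1 at 4.99 ± 0.24 and the Polycomb proteins PHC1 and CBX2 at 4.59 ± 0.30 and 3.67 ± 0.31. In the cholesterol and lipid synthesis list 7 of 15 members were higher and 0 lower, including HMGCS1, an early enzyme of the mevalonate pathway (2.47 ± 0.31), the fatty acid desaturase SCD (2.48 ± 0.38) and DHCR7, the last enzyme of cholesterol synthesis (2.06 ± 0.38). These 4 lists had adjusted p = 1.32e-05, 0.0301, 0.0359 and 0.0285 in this order, and adjusted p = 0.510, 0.506, 0.269 and 0.510 with an estimated correlation. Leaving out the second ESIMR90 array ended the call of the inhibitor list (adjusted p = 0.139) and of the cholesterol list (0.0746), which was also lost without the second IMR90 array (0.0715), with the beta-actin ratio as a covariate (0.0575) and with median centring (0.0681). Quantile normalisation ended the call of the inhibitor list (adjusted p = 0.0658), as did a filter above the median on all arrays (0.274) and 1 above the 75th percentile on 2 arrays (0.128), and a floor at the array median that of the DNA methylation and Polycomb list (0.0528).

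Antigen presentation and interferon genes were mostly lower in ESIMR90, with 11 of 22 called lower and 2 higher (14 lower when adjusted over the list alone). B2M, the light chain of class I molecules, was at −2.43 ± 0.24, whereas the interferon-induced membrane proteins IFITM1 (3.80 ± 0.23) and BST2 (at least 6.34-fold) were the 2 members called higher. Primed pluripotency genes were higher in 10 of 13 cases, including the transcription factors OTX2 (at least 42.8-fold) and ZIC2 (at least 131-fold), and lower in 2, the intermediate filament VIM (−2.76 ± 0.33) and the cytokine-like CYTL1 (at least 2.84-fold), named after their values were seen. The lists had adjusted p = 3.23e-04 and 0.00450, and adjusted p = 0.137 and 0.237 with an estimated correlation. The call of the primed list was lost when probe sets had to lie above the median on all 6 arrays (adjusted p = 0.285). Of the reprogramming factors, SOX2, NANOG and LIN28A were higher as above, KLF4 was lower (−2.65 ± 0.55, adjusted p = 0.0052), and MYC differed by −0.85 ± 0.27 (adjusted p = 0.033), under the minimum difference.

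The other lists did not pass camera, although single members did. Fry, which asks only for movement in 1 direction, kept all lists called above (adjusted p from 2.50e-05 for core pluripotency to 0.0203). It also passed most lists below, from 8.68e-04 (reprogramming factors) to 0.0456 (heat shock). Those that did not pass fry were mesoderm (0.110), trophoblast (0.195), metallothioneins (0.311), endoderm (0.657) and oxidative phosphorylation (0.687). Imprinted genes were called higher in 7 and lower in 8 of 24 cases (adjusted p = 0.488), with the maternally expressed long noncoding RNA MEG3 at least 29.8-fold lower and the phosphatase INPP5F at 3.06 ± 0.23. Metallothioneins were lower in 3 of 7 cases (adjusted p = 0.0577), with MT2A at −1.73 ± 0.34, and ectoderm and neural genes higher in 7 and lower in 1 of 10 (0.0607), with SOX3 at least 5.57-fold higher. Immediate early genes were lower in 4 and higher in 2 of 13 cases (0.120), with the phosphatase DUSP1 at −5.22 ± 0.25, and heat shock and unfolded protein response genes lower in 5 and higher in 3 of 17 (0.216), with HSPB1 at −2.85 ± 0.24. The glucose transporter SLC2A3 (3.75 ± 0.29) was 1 of 3 glycolysis genes called higher, with 2 lower, of 21 (0.726). Naive pluripotency genes were higher in 3 and lower in 3 of 8 cases (0.367), with KLF2 at least 11.7-fold lower. Endothelial genes were higher in 2 and lower in 1 of 6 (0.6005), with the VEGF receptor KDR at least 19.9-fold higher and the TGF-beta coreceptor ENG at least 18.8-fold lower. Called members, higher and lower, numbered 3 and 1 of 5 for reprogramming factors (0.212), 1 and 1 of 29 for oxidative phosphorylation (0.232), 1 and 0 of 5 for lung epithelium (0.539), 2 and 0 of 16 for genes near 20q11.21 (0.581), and 3 and 2 of 11 for genes reported to vary between iPS and ES lines (0.596). They numbered 2 and 0 of 7 for mesoderm (0.652), 3 and 1 of 6 for endoderm (0.752) and 2 and 0 of 10 for trophoblast (0.752). Blood and macrophage markers had 2 tested members, HBB and FCER1G, at 0.86 ± 0.61 and 0.50 ± 0.54, not called. Among these lists metallothioneins were called in 6 of 20 alternatives, including without the first ESIMR90 array (adjusted p = 0.00430) and without the first IMR90 array (0.0266). Without the first and the second IMR90 array the ectoderm list (adjusted p = 0.0292 and 0.0133) and the reprogramming factors (0.0292 and 0.0349) were called, and without the first ESIMR90 array the immediate early list (0.0448). For imprinted genes the median (0.35) differed in sign from the mean (−0.22) and the test.

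In all, 3374 genes were called higher and 2208 lower in ESIMR90 than in IMR90, 41.2% of the 13536 tested. The split depended on the scaling, because IMR90 arrays had lower medians: 60.4% of the calls were higher as deposited, 54.2% after quantile normalisation and 36.3% after median centring (2016 higher and 3541 lower). The median difference of all genes was 0.28 as deposited, 0.12 after quantile normalisation and −0.29 after median centring. Without the first IMR90 array 1457 genes were called lower, and with the beta-actin ratio as a covariate, chosen after seeing the data, 2050 were called higher and 1436 lower.

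**Figure D1:**
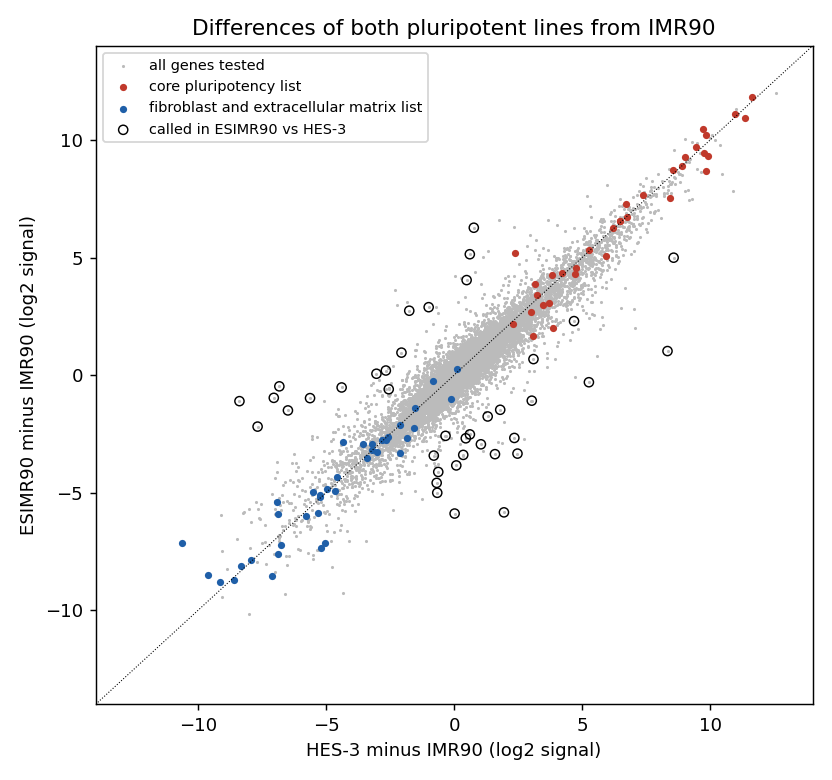
Log2 difference of HES-3 from IMR90 (horizontal axis) and of ESIMR90 from IMR90 (vertical axis), 1 point per tested gene, from means of 2 arrays per line; the dotted line marks equal differences. Core pluripotency genes (red) lay at the upper end and most fibroblast and extracellular matrix genes (blue) at the lower end of both axes, and the 39 genes called between ESIMR90 and HES-3 (circles) lay off the line.

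In the ES line, 8 of the 12 lists called for ESIMR90 against IMR90 were called too. In HES-3, 33 of 34 core pluripotency genes were called higher than in IMR90 (median 6.48), the exception being DPPA5 (2.38 ± 1.73, named after its value was seen). NANOG was at least 235-fold higher, LIN28A at least 364-fold, DPPA4 at least 277-fold, SOX2 at least 196-fold, CD24 at least 451-fold, TRIM71 at least 276-fold and L1TD1 at least 258-fold. POU5F1B (7.79 ± 0.22), MIR302B (7.43 ± 0.32), POU5F1P4 (6.97 ± 0.31), CXADR (6.75 ± 0.25) and DNMT3B (6.74 ± 0.28), with the limits given above, again led the genes measured in both lines. All 25 epithelial genes were called higher, including CDH1 (at least 243-fold) and EPCAM (8.18 ± 0.24). Fibroblast and matrix genes were lower in 35 of 38 cases (median −4.81). DCN was at least 220-fold lower, the fibrillar collagen COL3A1 at least 199-fold, MMP1 at least 198-fold, the surface protein TM4SF1 at least 181-fold and IGFBP7 at least 154-fold. LOX (−7.10 ± 0.32), the microfibrillar collagen COL6A3 (−6.88 ± 0.42), CD44 (−6.75 ± 0.42), the tight junction protein CLDN11 (−6.24 ± 0.38) and ACTA2 (−5.79 ± 0.42) fell furthest among genes measured in both lines.

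Among the remaining groups, 16 of 18 mesenchymal genes were lower in HES-3, including the repressor of E-cadherin ZEB2 (at least 8.40-fold), as were 14 of 17 positional genes, including the homeobox factor MEIS2 (−4.64 ± 0.48), and all 12 contractile genes. Replication and mitosis genes were higher in 19 of 36 cases, with the origin licensing factor CDT1 at 2.93 ± 0.42, the spindle checkpoint kinase BUB1B at 1.68 ± 0.26 and MCM3 at 1.83 ± 0.29, and primed pluripotency genes higher in 9 and lower in 2 of 13. The core, fibroblast, epithelial and mesenchymal lists had adjusted p = 1.51e-17, 7.13e-21, 5.46e-14 and 5.69e-09, and adjusted p = 0.0564, 0.167, 0.0688 and 0.0688 with an estimated correlation. For the positional, contractile, replication and primed lists adjusted p was 4.21e-08, 4.83e-08, 0.00260 and 0.00841, and adjusted p = 0.338, 0.261, 0.643 and 0.310 with an estimated correlation. Without the first HES-3 array, which leaves the array with the beta-actin ratio of 16.5, the replication list was not called (adjusted p = 0.0586), and with probe sets above the median on all 6 arrays the primed list was not (0.379). The other 20 lists were not called, with adjusted p from 0.0559 (antigen presentation and interferon) to 0.902 (endothelial). They included 4 lists called for ESIMR90: antigen presentation, DNA methylation and Polycomb (adjusted p = 0.0795), cell cycle inhibitors and p53 targets (0.203) and cholesterol and lipid synthesis (0.213). Fry passed these 4 (adjusted p = 0.0108, 7.44e-04, 0.0458 and 0.0458) and kept all lists called by camera (2.95e-05 for core pluripotency to 0.0419 for replication). Of the 20 lists, fry did not pass mesoderm (0.0598), naive pluripotency (0.393), oxidative phosphorylation (0.440), endoderm (0.680) and metallothioneins (0.875). With other settings the antigen presentation list was called in HES-3 too in 7 of 20 alternatives (smallest adjusted p = 0.0151, with a floor at the array median), among them without either ESIMR90 array (0.0332 and 0.0310), and the DNA methylation and Polycomb list in 4 of 20 (smallest adjusted p = 0.00924). Oxidative phosphorylation was called without the first HES-3 array (adjusted p = 0.00499), and the reported list and the reprogramming factors without the first IMR90 array (0.0492 and 0.0499). A call in 1 line and not in the other is no test of a difference, which the direct comparison of the lines below gives. The median differed in sign from the mean or the test for naive pluripotency (median 0.31, mean −0.37), trophoblast (median −0.39, mean 0.12), metallothioneins (median −0.29, mean 0.17) and endothelial genes (median 0.22, lower by the test).

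KLF4 and MYC were both lower in HES-3 than in IMR90, at −2.09 ± 0.55 and −1.20 ± 0.27 (adjusted p = 0.015 and 0.0081). SLC2A3 was at 4.997 ± 0.292, the trophoblast and germ cell factor TFAP2C at least 17.3-fold higher and KDR at least 38.3-fold higher. Of the genes reported to vary between iPS and ES lines, 8 of 11 were called higher in HES-3 than in IMR90 and 2 lower, with the 3 of smallest adjusted p being TCERG1L (at least 5.55-fold), TMEM132D (at least 5.84-fold) and the potassium channel subunit DPP6 (at least 3.78-fold). Over all genes, 3466 were called higher and 2044 lower (40.7% of those tested). The share called higher was 62.9% as deposited, 56.4% after quantile normalisation and 37.3% after median centring (2142 higher and 3597 lower). The median difference of all genes was 0.28, 0.11 and −0.34 under these scalings. Adding the beta-actin covariate left 1100 higher and 763 lower. Because the ratio was lower on both IMR90 arrays than on any other, this loss cannot be assigned to RNA quality.

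**Figure D2:**
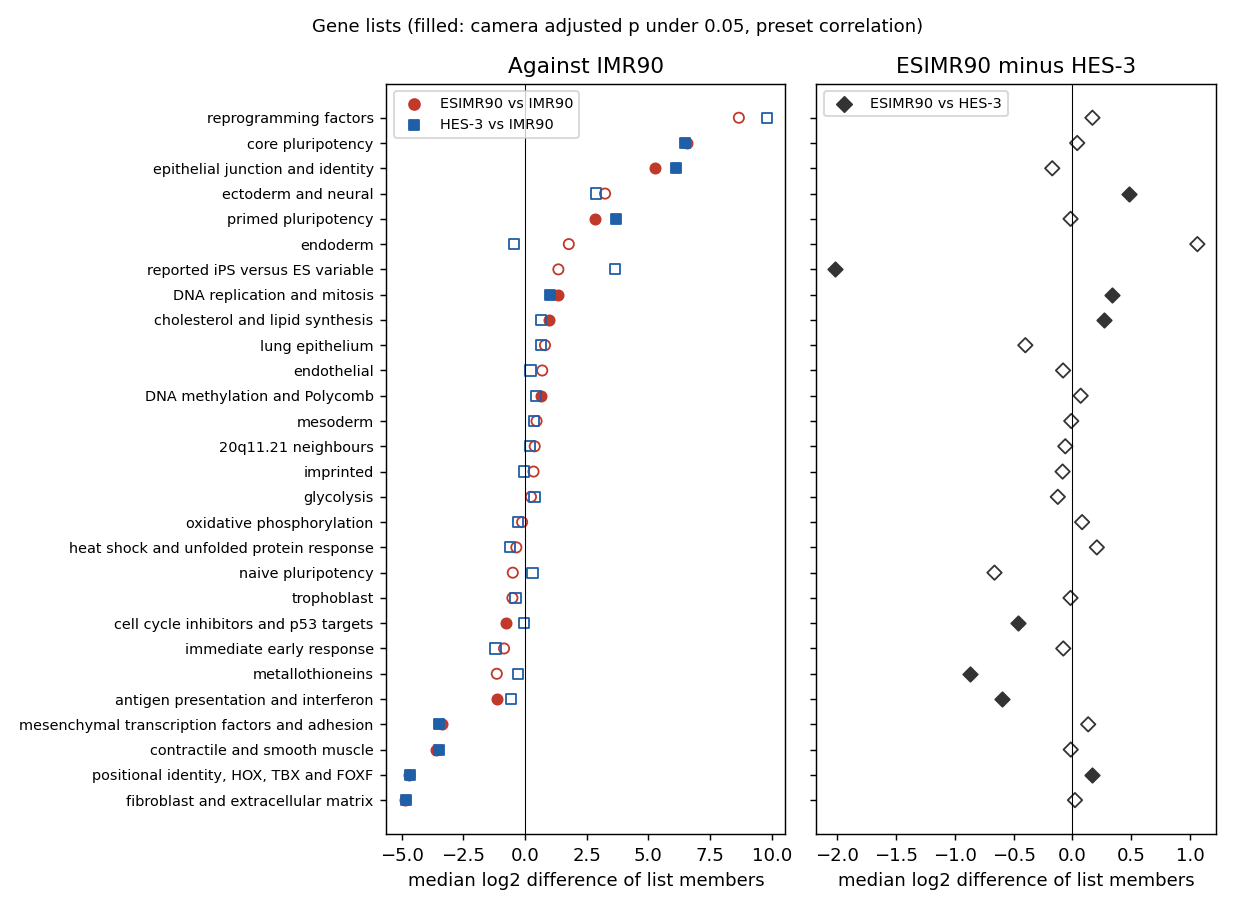
Median log2 difference of the tested members of each gene list with at least 5 of them, for both pluripotent lines against IMR90 (left) and for ESIMR90 minus HES-3 (right); filled symbols mark lists with a camera adjusted p under 0.05 with the preset correlation. The medians ran from −4.88 to 9.82 against IMR90 and from −2.02 to 1.06 between the pluripotent lines.

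Both pluripotent lines departed from IMR90 in largely the same genes. Of the 5510 genes called between HES-3 and IMR90, 4622 (83.9%, 95% Wilson interval 82.9 to 84.8) were called in the same direction in ESIMR90 and 10 in the opposite one. The interval treats genes as independent, which they are not, so it does not measure the spread between arrays. Between ESIMR90 and HES-3 themselves, 24 of the 5510 (0.436%) were called. With 0 for the IMR90 level of each gene and 1 for its HES-3 level, ESIMR90 lay at a median of 0.947 (quartiles 0.794 and 1.08). The median was 0.934 for genes higher in HES-3 than in IMR90 and 0.978 for those lower. Choosing genes by their HES-3 call favours large HES-3 differences, so a median under 1 may come from the choice alone. Both comparisons against IMR90 called 2899 genes higher and 1723 lower, against 864 and 333 for independent lists of these sizes. Across genes the differences correlated at r = 0.947, against a mean of 0.501 (0.470 to 0.533) in 100 simulated draws of unchanged lines against the same IMR90 arrays. The covariance was 4.13 against 0.111 in the simulation, a difference of 4.01. With 2 IMR90 arrays the shared arrays could not be split into parts of at least 2, so part of the excess over independent lists may come from them. The share of 83.9% was 68.7% without the first ESIMR90 array and 88.6% without the second HES-3 array.

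Between the iPS and the ES cells, few genes differed. ESIMR90 had 16 genes called higher and 23 lower than HES-3, 0.288% of those tested, against 1138 genes at an unadjusted p under 0.05. Several of these differences were large. The endothelin receptor EDNRB, a gene of neural crest cells, was at least 37.6-fold higher in ESIMR90 and low in IMR90 (mean signals 4385, 97.0 in HES-3 and 56.9 in IMR90), as was POTEM, of a family of primate-specific ankyrin repeat proteins with closely similar members (at least 14.1-fold). The mitochondrial proteins CHCHD2 (at least 30.7-fold) and DNAJC15 (at least 17.4-fold) and the membrane protein TMBIM4 (at least 20.1-fold) were low in HES-3 alone, with mean signals of 79.9, 13.1 and 73.7 against 16362, 4379 and 6634 in IMR90. ANKRD20A11P, an ankyrin repeat pseudogene (3.55 ± 0.40), CUL4B, a ubiquitin ligase scaffold (3.09 ± 0.29), CEBPZOS (2.86 ± 0.30) and the ephrin receptor EPHA4 (1.95 ± 0.27) were the other named genes higher in ESIMR90.

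Among genes lower in ESIMR90, MAGEA6, a cancer-testis antigen of a family with closely similar members, was at least 32.6-fold lower, the zinc finger gene ZNF667 at least 15.3-fold, its antisense neighbour ZNF667-AS1 at least 11.9-fold, the protocadherin PCDHB5 at least 14.5-fold and the noncoding RNA LINC00664 at least 12.0-fold. ZNF562 (−3.99 ± 0.31), TOMM5, of the mitochondrial import complex (−3.90 ± 0.32), the homeobox factor IRX2 (−3.58 ± 0.53), ZNF22 (−3.07 ± 0.27) and ZNF850 (−2.42 ± 0.34) were the largest decreases among genes measured in both lines. The adjusted p-values of the 39 genes lay between 5.34e-04 and 0.0468. IMR90 differed from HES-3 in the same direction for 24 of the 39 (61.5%, Wilson interval 45.9 to 75.1) and in the opposite one for 0. This interval too treats genes as independent and does not measure the spread between arrays. Of the 16 genes higher in ESIMR90, 12 were also higher in IMR90 than in HES-3, against 2.42 for independent lists, and of the 23 lower, 12 were also lower in IMR90, against 5.89. The shared HES-3 arrays add to both overlaps, and to the 61.5%, which was 37.5% with the beta-actin covariate. Over all genes ESIMR90 and IMR90 lay on the same side of HES-3 in 56.0%. The simulated draws of unchanged lines gave a mean of 66.7% (65.9 to 68.0). They hold no real difference of IMR90 from HES-3, unlike the data, so they are no reference for this share. The part of the overlaps that comes from the shared HES-3 arrays is therefore unknown. The overlaps are given as counts and not as evidence of retained expression. Of the 23 lower genes, 18 were also lower in ESIMR90 than in IMR90, and of the 16 higher, 5 were higher than in IMR90 too.

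**Figure D3:**
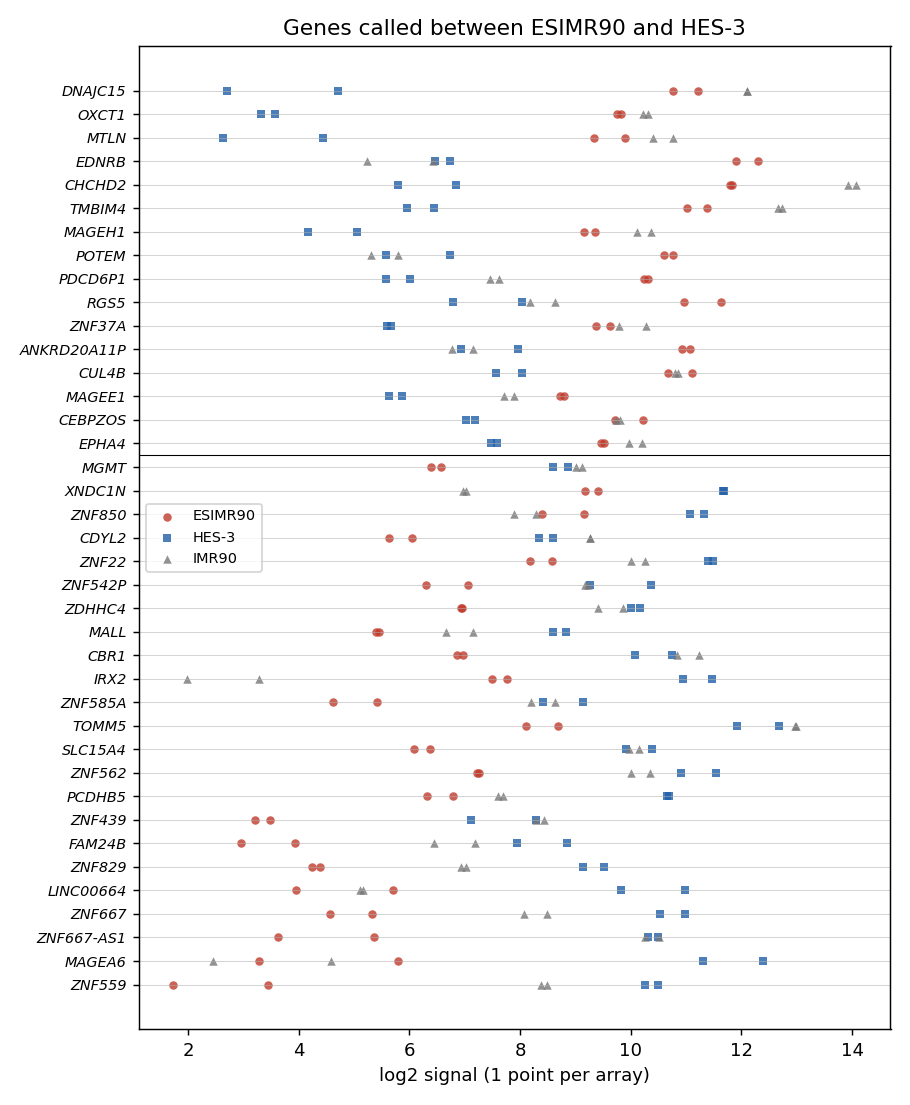
Log2 signal of the 39 genes called between ESIMR90 and HES-3, 1 point per array and 2 arrays per line; the 16 genes above the horizontal line were higher in ESIMR90 and the 23 below it lower. In 12 of the 16 genes IMR90 was also called higher than HES-3, and in 18 of the 23 ESIMR90 was called lower than both other lines.

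Single arrays moved these counts. Without the first HES-3 array, which leaves the array with the beta-actin ratio of 16.5, 161 genes were called higher and 131 lower, and 36 of the 39 remained. Without the second, 15 and 13 were called, and 26 of the 39 remained. Without the first ESIMR90 array 4 and 11 were called, and without the second 4 and 13. For 12287 genes (90.8%) the difference was under 1 in size, and for 5109 (37.7%) its 95% confidence interval lay within ±1, so for most genes a 2-fold difference was not excluded. No shift of a whole chromosome was called: 0 of 22 autosomes passed camera, the smallest p being that of chromosome 19 (0.0319, adjusted p = 0.702, median −0.10). Without the first ESIMR90 array chromosome 19 was called lower (adjusted p = 0.0293, median −0.17).

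The core pluripotency and fibroblast lists were not called between ESIMR90 and HES-3 with all arrays. The core pluripotency list had a median of 0.04 and a mean of −0.07, with 0 of 34 members called (adjusted p = 0.996), and the fibroblast list a median of 0.02 with 0 of 38 called (adjusted p = 0.996, 2 lower when adjusted over the list alone). The fibroblast list was called higher without the first ESIMR90 array (median 0.24, adjusted p = 0.0420). The primed pluripotency list had a median of −0.02 (adjusted p = 0.728) and the naive list −0.66 (adjusted p = 0.149), with 2 of 8 members positive. Without a filter on dim probe sets the naive list was called lower (median −0.84, adjusted p = 0.0198), and with a floor at the array median its median was −0.26. Of the reprogramming factors, NANOG was at −1.16 ± 0.65 (adjusted p = 0.72), KLF4 at −0.56 ± 0.55 (0.85), SOX2 at 0.40 ± 0.26 (0.78), MYC at 0.35 ± 0.27 (0.82) and LIN28A at 0.17 ± 0.64 (0.97). The smallest adjusted p-values among the named list members that were not called were those of the angiopoietin receptor TEK (at least 3.66-fold higher, 0.068), the imprinted ZDBF2 (−1.99 ± 0.35, 0.094) and TMEM132D (at least 3.93-fold lower, 0.12).

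Of the 28 tested lists 8 were called between the pluripotent lines with the preset correlation, without a called member. All 11 genes reported to vary between iPS and ES lines lay lower in ESIMR90, with a median of −2.02 and adjusted p = 2.10e-06 (adjusted p = 0.242 with an estimated correlation). The median was −1.35 with a floor at the array median, since leading members were dim in ESIMR90, and ranged over the alternatives from −2.71 to −0.62, the latter under the 75th percentile filter that left 5 members (largest adjusted p = 0.0150). When adjusted over the list alone 6 were lower, including TMEM132D, TCERG1L (at least 3.73-fold) and catalase (CAT, −2.02 ± 0.43). Antigen presentation and interferon genes had a median of −0.59 and adjusted p = 3.43e-05 (adjusted p = 0.242 with an estimated correlation), and 2 were lower when adjusted over the list alone, the immunoproteasome subunit PSMB8 (−1.54 ± 0.34) and the peptide transporter TAP1 (−1.37 ± 0.30). With fry these lists had adjusted p = 0.0462 and 0.00226. The other called lists did not pass fry, with adjusted p from 0.502 (cell cycle inhibitors and p53 targets) to 0.836 (positional identity). Replication and mitosis genes lay higher by a median of 0.34, with 31 of 36 positive (adjusted p = 5.35e-05, and adjusted p = 0.547 with an estimated correlation). MCM4 (1.22 ± 0.36) and the survivin gene BIRC5 (1.04 ± 0.32) had the smallest adjusted p there, 0.35 and 0.40. Without the second HES-3 array, with the beta-actin ratio of 16.5, the median was 0.03 and the list was not called (adjusted p = 0.387), and without the first it was 0.72.

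The 5 other lists called with the preset correlation were each lost without at least 1 array. Metallothioneins, which bind zinc and copper, had a median of −0.87 (adjusted p = 0.00143), with MT1F at −1.49 ± 0.42, and cholesterol and lipid synthesis genes a median of 0.27 (0.00319), with the farnesyl diphosphate synthase FDPS at 0.64 ± 0.23. Cell cycle inhibitors and p53 targets had a median of −0.46 (0.0286), with the cyclin-dependent kinase inhibitor CDKN1C at −1.26 ± 0.36. Positional identity genes had a median of 0.17 (0.0379), which was −0.05 with a floor at the array median. Its 3 members of smallest p, FOXF1, HOXB6 and HOXB3, lay at or under the array medians on both HES-3 arrays, and HOXB6 on both ESIMR90 arrays too. The last of the 5 was ectoderm and neural genes, with a median of 0.49 (0.0463) and the neuronal microtubule regulator STMN2 at 2.42 ± 1.15. With an estimated correlation the positional list had adjusted p = 0.744 and the 4 others adjusted p = 0.547. Without the second ESIMR90 array the adjusted p of these 5 lists, in the order given, was 0.254, 0.0865, 0.554, 0.261 and 0.202, and without the first HES-3 array 0.394, 0.592, 0.394, 0.129 and 0.0881. Their medians in that order were −0.32, 0.20, −0.06, −0.43 and 0.43 without the second ESIMR90 array and −0.38, 0.15, −0.43, 0.70 and 0.71 without the first HES-3 array, so some calls ended with a smaller shift and others with 1 as large or larger. Without the first ESIMR90 array the metallothionein median was −1.37 and the positional 1.54, and without the second HES-3 array the cholesterol median was 0.51, the positional 0.12 and the ectoderm 0.26. Without the second HES-3 array the positional list had adjusted p = 0.102 and the ectoderm list 0.319, and without the first ESIMR90 array the ectoderm list 0.0575. Quantile normalisation (adjusted p = 0.0612), a floor at the array median (0.327), a fit of only the groups compared (0.0877) and the beta-actin covariate (0.226) also ended the call of the positional list. Median centring (adjusted p = 0.0509), no filter (0.230), the replicate block (0.0516) and the beta-actin covariate (0.147) ended that of the ectoderm list. The remaining 20 lists were not called, with adjusted p from 0.0707 (endoderm, median 1.06) to 0.996. Endoderm genes were called in 7 of 18 alternatives, and their median was −0.32 without the second ESIMR90 array (adjusted p = 0.954). Without the first ESIMR90 array the endoderm list was called higher (median 1.77, adjusted p = 2.69e-05), as were the mesenchymal (0.31, adjusted p = 0.0150) and mesoderm (0.70, adjusted p = 0.0461) lists. Without the first HES-3 array the oxidative phosphorylation list was (0.33, adjusted p = 0.00305). The median differed in sign from the mean or the test for core and primed pluripotency, reprogramming factors, fibroblast, contractile, imprinted, mesoderm, endothelial, immediate early and 20q11.21 genes. In every list 0 members were called over all genes tested, while 1138 of all genes had an unadjusted p under 0.05.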

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

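The beta-actin ratio as a covariate was the only alternative chosen after the data were seen; all others were planned and all were run. The direction and call of the core pluripotency, fibroblast, epithelial, mesenchymal, positional and contractile lists against IMR90 held in every alternative that gave them a value except with an estimated correlation. The estimated correlation rests on 3 residual degrees of freedom, so its losses cannot decide whether correlated genes made these calls. Of the values of named genes called with all arrays, 71, 87 and 56 fell short of the threshold (ESIMR90 against IMR90, HES-3 against IMR90, ESIMR90 against HES-3), against 1693, 1652 and 314 that kept direction and call. For called lists these numbers were 22, 10 and 35 against 241, 165 and 136. Calls were gained too, in 12, 14 and 19 values of named genes and 29, 37 and 13 of lists not called with all arrays. Leaving out an array leaves a lone sample, which is assumed to vary like the other groups. Dim signals limit what can be seen, and the filters test fewer genes by construction (9672 above the median on all 6 arrays, 9098 above the 75th percentile). Lists left with fewer than 5 members under a stricter filter, the reported, positional and ectoderm lists among them, had no value there. The cause of the other changes was not tested.

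Genes called higher in ESIMR90 than in IMR90 (3374) numbered 2016 with median centring, 1903 and 2140 with the 2 stricter filters, 1534 with treat, 2050 with the beta-actin covariate and 7534 as probe sets. Those called lower (2208) numbered 3541 with median centring, 1001 with treat, 1436 with the covariate, 4635 as probe sets and 1457 to 2332 with 1 array left out. For HES-3 against IMR90 the genes called higher (3466) numbered 2142, 1914, 2097, 1684, 1100 and 7724 under the same 6 alternatives, and those called lower (2044) 3597 with median centring, 899 with treat, 763 with the covariate and 4457 as probe sets. For ESIMR90 against HES-3 the genes called higher (16) numbered 4 with signals above the median on all arrays, 37 with a pseudocount, 25 with a floor and 4 to 161 with 1 array left out. Those called lower (23) numbered 4, 56, 45 and 11 to 131 under these, 12 with treat and 11 with the covariate.

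The share of genes called in HES-3 and in the same direction in ESIMR90 (83.9%) was 82.4% with quantile normalisation, 82.5% with median centring, 81.1% without a filter, 82.2% and 87.4% with the stricter filters, 80.8% with a pseudocount, 80.9% with a floor, 85.6% with only the groups compared, 96.4% with the covariate and 68.7% to 88.6% with 1 array left out. The correlation of the differences (0.947) was 0.895 without a filter, 0.963 with the 75th percentile filter and 0.911 to 0.948 with 1 array left out. The share of ESIMR90 and HES-3 differences with IMR90 on the side of ESIMR90 (61.5%) was 37.5% with the covariate. Leaving out 1 array gave 0 to 1 shifted chromosomes, the 1 being chromosome 19 without the first ESIMR90 array.

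With the replicate number as a block, 3471 and 2279 genes were called for ESIMR90 against IMR90, 3582 and 2103 for HES-3 against IMR90 and 20 and 32 for ESIMR90 against HES-3, with 5545 of 5582, 5478 of 5510 and 39 of 39 calls kept. The labels do not say that a number marks a shared culture or day. Deviations of arrays of the same number from their line's mean correlated at 0.202, 0.0869 and 0.00562, so the numbers were not taken to pair the samples. A step shared by number is not excluded, because the second array of each line had the higher median signal. Its Cre control probe set was brighter too: 44392 against 33964 in ESIMR90, 49147 against 29458 in HES-3 and 31398 against 24621 in IMR90.

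Over all called genes the sign turned for 61 in ESIMR90 and 70 in HES-3 against IMR90 when probe sets without a suffix were preferred. With the mean of probe sets it turned for 27 and 31. Of called genes with several kept probe sets, 88.7% and 86.2% had the same sign in all of them, and 42 and 70 genes had probe sets called both ways. For ESIMR90 against HES-3 these values were 94.4% and 0. Among named genes and lists, the direction of a test turned with a call on at least 1 side, or a called difference changed sign, in 7 cases. Between ESIMR90 and HES-3 the median of the fibroblast and extracellular matrix list was 0.24 without the first ESIMR90 array (−0.36 to 0.24 with 1 array left out), where it was called higher. There the test's direction turned (lower with all arrays), not the sign of the median. The median of the positional list was −0.43 without the second (−0.43 to 1.54). Medians of lists not called with all arrays also changed sign with 1 array left out, ranging from −0.32 to 1.77 for endoderm, −0.16 to 0.33 for oxidative phosphorylation, −0.53 to 0.60 for contractile and −0.08 to 0.31 for mesenchymal genes, among others. For HES-3 against IMR90, fry called the trophoblast list (median −0.39) and the endothelial list (median 0.22) higher, where camera gave lower and no call. QNG1 in ESIMR90 against IMR90 was −1.38 as the mean of its probe sets (adjusted p = 0.0947) and −4.12 when probe sets without a suffix were preferred (adjusted p = 0.0206), against 1.35, and B2M in HES-3 against IMR90 was 0.46 with that preference (adjusted p = 0.588), against −2.02.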

Other observations

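In this part the scan of gene families, the tests of 3' bias for both groups of single genes, the choice of other probe sets through IMR90 or without a choice, the test of a variant shared with IMR90 and the tests of fibroblasts and of an incomplete change were chosen only after the results were seen; the tests of other probe sets, of the zinc finger genes of chromosome 19 and of 3' bias for the gene lists were written before theirs. Genes were grouped by the letters of their symbols into 214 families of at least 8 tested members and tested with camera in each comparison, adjusted over the families. The annexins, membrane-binding proteins of calcium signalling, were lower in both pluripotent lines than in IMR90, with 9 of 13 called lower in ESIMR90 (median −2.39, adjusted p = 0.00216) and 8 of 13 in HES-3 (median −2.32, adjusted p = 7.95e-04). In ESIMR90 the genes with POU symbols (7 of 8 called higher, median 4.43, adjusted p = 0.0164), the IGSF immunoglobulin superfamily genes (8 of 8, median 4.90, adjusted p = 0.0271) and the MCM replication genes (9 of 11, median 2.06, adjusted p = 0.0271) were higher. The POU family includes POU5F1B and POU5F1P4, whose probe sets may read the same transcript, so its members are not all separate. Zinc finger genes with ZNF symbols were higher in HES-3 than in IMR90, with 166 of 419 called higher and 18 lower (median 0.88, adjusted p = 0.00379). With an estimated correlation none of these families in these comparisons passed (adjusted p = 0.966 in ESIMR90 and 0.987 in HES-3). That repeat rests on 3 residual degrees of freedom. Camera with it gave an unadjusted p = 0.00203 even for the core pluripotency list in ESIMR90 against IMR90. All 34 tested members of that list were called, and its estimated correlation (−0.0169) lay under the preset one. A loss in this repeat over 214 families therefore cannot decide whether correlated genes made these calls.

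Between the pluripotent lines the scan called 1 family, the protocadherin beta genes, clustered adhesion genes of neurons. All 12 tested members lay lower in ESIMR90 than in HES-3, with a median of −1.62 (adjusted p = 1.11e-06, unadjusted p = 0.0344 and adjusted p = 0.921 with an estimated correlation). Only PCDHB5 was called by itself (at least 14.5-fold lower, adjusted p = 0.00153), and PCDHB15 (at least 3.50-fold lower, adjusted p = 0.181) came next. The median was −1.21 without the second HES-3 array and ranged over the 22 alternatives from −2.27 to −0.26, both extremes under filters that left 2 members, and at −0.26, with signals above the median on every array, those 2 did not pass camera at 0.05 even unadjusted. The median was −0.95 with a floor at the array median and −0.82 with a pseudocount. Of the 22 alternatives, the 2 other variance models, no minimum difference and treat repeat the main test of a set by construction. The members are alike in sequence, so signals shared between their probe sets were not separated here.

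A first pattern was the 12 genes called lower in HES-3 than in both ESIMR90 and IMR90, among them CHCHD2, DNAJC15, TMBIM4, OXCT1 and CUL4B. A sequence variant of HES-3 under a single probe set would leave the other probe sets of these genes alike, but 12 other probe sets of 7 of the genes, those above the array median on both ESIMR90 arrays, also differed, by a median of 2.53 (lower quartile 1.93). That choice favours a difference, by 0.05 over all other genes. With probe sets chosen through IMR90 instead the median was 2.06 (13 of 6 genes), and without a choice 1.98. These values argue against a variant under a single probe set for those 7 genes. They leave it open for the other 5, CHCHD2, MAGEH1, MTLN, OXCT1 and ZNF37A. Probe sequences were not mapped here, so a variant in sequence shared by several probe sets of a gene stays open for all 12. A fit of all genes without the second HES-3 array called the 12 genes other than EPHA4 and MAGEE1, and the 3' bias of that array cannot have made those calls. For EPHA4 and MAGEE1 the median difference was 2.40 without that array and 2.48 with it (1.95 and 1.92 with dim signals at the array median). Genes chosen with all arrays had to differ on the remaining arrays too. This size therefore cannot decide on that bias, which stays open for these 2 genes. A low level of these transcripts in HES-3, from the line's genotype or from its state, may account for the pattern and stays open, because 1 ES line cannot separate line from cell type.

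Another pattern was the 18 genes called lower in ESIMR90 than in both other lines, many of them zinc finger genes; ZNF symbols made up 10 of all 23 genes called lower than in HES-3, a share noticed among these same genes, so that a test on them decides nothing, with ZNF667 and its antisense neighbour counted apart, and 9 of the 10 lay on chromosome 19. A fault or cross-hybridisation of single probe sets is argued against for 6 genes by other probe sets above the array median on both HES-3 arrays, 8 of 7 genes with a median of 4.26 (lower quartile 2.72; 3.61 for 7 chosen through IMR90, and 2.62 with a lower quartile of 0.10 for 13 without a choice), and stays open for CDYL2 (0.0627) and for the 11 genes with no such probe set. Sequence shared between the probe sets of a gene was not checked for these genes either. A variant under the probe sets that ESIMR90 shares with IMR90 is argued against for 9 of the 10 ZNF genes, which were chosen without IMR90. Over the 10, IMR90 minus ESIMR90 had a median of 3.14 (lower quartile 2.56). Such a variant stays open for ZNF850 (−0.68), a single gene. A fit without the second HES-3 array called the 18 genes other than CDYL2, FAM24B, MALL, MGMT, ZNF585A and ZNF439, and the 3' bias of that array cannot have made those calls. Without it the first 5 of the genes not called had a median difference of 3.16, against 3.28 with all arrays (1.77 and 1.89 with dim signals at the array median). ZNF439, near the array median on the other HES-3 array, differed by 3.77 without the second. Genes chosen with all arrays had to differ on the remaining arrays too, so these sizes cannot decide on that bias. It stays open for the 6 genes not called. A lower level of all zinc finger genes of chromosome 19 was borne out in direction, with 152 of 198 lower in ESIMR90 and a median of −0.32 (camera p = 4.61e-09, and p = 0.0694 with an estimated correlation), whereas the 221 on other chromosomes had a median of −0.05 (p = 0.492); it was −0.29 over the 189 not called (p = 4.55e-06, and p = 0.117 with an estimated correlation) and ranged from −0.42 to −0.19 over the alternatives, the latter without the second ESIMR90 array. So small a shift does not reach the differences of the called genes, for which silencing of single genes in ESIMR90 during or after reprogramming may be a candidate explanation, untested here.

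A further pattern was the 8 gene lists shifted between ESIMR90 and HES-3. Fibroblasts in the ESIMR90 cultures are argued against for 7 of them, because the fibroblast and extracellular matrix list lay at a median of 3.39% of its IMR90 signal (upper quartile 14.5%; COL1A1, FN1 and COL1A2, the brightest in IMR90, at 37.8%, 10.8% and 10.4%, with similar levels in HES-3, where 25 of the 38 members lay above the array medians), and cells at that share would reach at least 50% of the shift, in its direction, for 0 of the 7 lists. They stay open for the positional list, whose median that share would raise by 0.86, because its genes were dim; an incomplete change of fibroblast expression stays open for the reported and positional lists, the 2 of the 8 whose medians lay toward IMR90, and the fibroblast list itself went both ways (20 of 38 above HES-3, medians from −0.36 to 0.24 with 1 array left out), while the mesenchymal list was called higher without the first ESIMR90 array (0.31, adjusted p = 0.0150). For the 3' bias of the second HES-3 array, 5 of the 8 lists kept their call and direction without that array, between the bounds set for and against it. The replication, positional and ectoderm lists did not. Lists also lost their call without the first HES-3 array or the second ESIMR90 array, so this count cannot decide whether the bias contributed. The reported and the antigen presentation lists kept their direction and call without any 1 of the 6 arrays, with medians from −2.66 to −1.85 and from −0.59 to −0.43. The IMR90 arrays do not enter this difference, so only leaving out an ESIMR90 or HES-3 array could change these medians. Both lists were lost with an estimated correlation, which was 0.039 for the reported list and −0.035 for the antigen presentation list, the latter under the preset 0.01. That repeat rests on 3 residual degrees of freedom, so its loss is not evidence that correlated genes made the antigen presentation call. A difference between the lines may underlie these lists only as a hypothesis, and no biological explanation beyond the identity of the lines was tested.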
